A study of Homo sapiens with 3 samples.

How the data were processed

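Gene expression was measured in Caco-2 cells, a human colorectal line that takes on features of small-intestinal enterocytes when kept confluent. The cells had been differentiated for 21 days on permeable inserts, per the labels' protocols. Total RNA was labelled with biotin and hybridised to 3 one-colour Affymetrix arrays. Of these, 2 arrays were controls and 1 array came from cells co-cultured for 4 hours with Bifidobacterium animalis subsp. lactis BB-12, a probiotic strain. Each array held RNA pooled from 3 wells, which the design text calls technical replicates. The labels do not say whether the control pools came from separate cultures. The p-values of single probe sets therefore measure only the spread between these control pools, which may be technical. The labels disagree on the control. The sample descriptions place it before the incubation (0 hours), whereas the treatment protocol describes wells in the same set-up without bacteria.

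The deposited values are log2 expression per probe set. GCRMA and limma are named in the submitters' processing notes without versions or roles, and the values share a floor at 2.22 on all 3 arrays. Background correction and between-array normalization are therefore taken to be part of the deposited log2 values. Of 54675 probe sets, 62 are array controls. Symbols came from the platform annotation. It gave 1 gene for 41091 probe sets, several genes for 1801 and none for 11721. Of the probe sets with 1 gene, 41037 had a gene ID in the RefSeq gene table, and 0 symbols needed an update. Probe sets with several genes or none were tested and counted but not named. Genomic positions of the probes were not used here. The number of arrays limits the precision.

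Array controls were left out, and the 23153 probe sets with a mean log2 of at least 4 over the 3 arrays were tested. The test was lmFit and eBayes (limma 3.58.1 in R 4.3.3, default settings) on the log2 values, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The lone co-culture array adds no residual degree of freedom. It is assumed to vary like the controls, and the spread rests on 1 residual degree of freedom per probe set plus the empirical Bayes prior. A size rule without a test was used beside it: at least 2-fold higher, or at least 2-fold lower, than each control array separately. A gene is represented by its probe set with the highest mean among those annotated with 1 symbol.

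A total of 36 gene lists were fixed before the data were examined, as were the main test, the rule for named genes and most alternatives. Their 783 symbols all matched the gene table, 709 had a probe set with 1 gene and 567 were tested. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. At a preset correlation camera sets the members against all other genes, so list p-values take genes, not arrays, as the units. With an estimated correlation it is limited to the 1 residual degree of freedom and has little power. Each list median was also set against 10000 random lists matched on mean expression in 10 bins. The genes named are the 12 largest positive and 12 largest negative differences that meet the size rule, and up to 4 members per list. The rule asked first for genes past the adjusted p. Since none passed, all 24 were filled in by size alone. Genes named outside this rule are marked as chosen after their values were seen.

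The procedure was tested on simulated data over 23153 probe sets with 200 changed ones. With variances drawn from the fitted prior, the test called 0% of the probe sets changed 16-fold, while the size rule found 98% of them and also passed 529 unchanged ones. With residuals of the control pair redrawn between probe sets of like level, the test called 94% of those changed 4-fold and 0% of those changed 2-fold. The size rule then passed 6 unchanged probe sets. This redrawing does not keep the equal control values that single probe sets have in the data, so the 94% need not hold for the data. A list of 20 genes shifted by 0.5 was called under both noise models, and 0 of 20 unshifted lists were called. The noise was drawn independently for each probe set, so this does not show how often lists of correlated genes would be called without a shift.

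Alternatives covered the filter (none, or a mean log2 of at least 6), repeated quantile normalization, median-centring, the eBayes prior, stricter thresholds, probe sets with shared sequence left out, the mean over probe sets, a pseudocount of 16, an estimated correlation for the lists and each control left out. Leaving out probe sets with equal or nearly equal control values, at 3 tolerances, and the filter on the control mean were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.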

Results

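Expression of 54675 probe sets was measured in differentiated Caco-2 cells on 2 control arrays and 1 array of cells co-cultured for 4 hours with the probiotic Bifidobacterium animalis subsp. lactis BB-12. The 3 arrays were alike in distribution. Between 29.8% and 30.1% of probe sets lay at the floor, and the median of tested probe sets was 7.69 and 7.60 on the control arrays and 7.66 on the co-culture array. The 3-prime minus 5-prime difference of the ACTB control probe sets, a sign of RNA integrity, was 1.01 and 1.25 in the controls and 0.95 in the co-culture array. Across tested probe sets Pearson's r was 0.994 between the controls, and 0.988 and 0.986 between the co-culture array and control replicates 1 and 2. Genes are not independent replicates in these values.

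The comparison asked which transcripts of the epithelial cells differed after contact with the bacteria. Chemokine genes stood furthest above the controls. CCL20, which attracts dendritic cells and lymphocytes through CCR6, had a log2 level of 13.06 in the co-culture array against 6.76 ± 0.12 (SD, n = 2) in the controls, a 78.7-fold difference. The neutrophil-attracting CXCL1, CXCL3 and CXCL2 were 45.9-fold, 30.5-fold and 10.1-fold higher, CXCL10 was 25.6-fold higher and the monocyte attractant CCL2 was 8.29-fold higher. The controls of CXCL1, CXCL10 and CCL2 averaged below the filter level of 4, and CXCL1 lay at the floor in control replicate 1, so these folds stand over background-level signal and are uncertain in size. With a pseudocount of 16, CXCL1, CXCL3, CXCL10 and CCL2 were 14.0-fold, 19.0-fold, 9.82-fold and 4.48-fold higher. On the low side, EGR1, an immediate-early transcription factor, was 8.87 in the co-culture array against 12.22 ± 0.0048 (SD, n = 2) in the controls, 10.2-fold lower. POFUT4, a protein O-fucosyltransferase, was 5.75-fold lower.

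None of these single genes passed the adjusted test at the main settings. limma called 0 of 23153 probe sets, with a lowest adjusted p of 0.405, while 2784 probe sets had an unadjusted p under 0.05 where 1158 were expected by chance. The chance count is nominal. It was also exceeded with control replicate 2 set against the other arrays, but not with control replicate 1, although the spread then included the co-culture array. The count of calls depended strongly on the setting. It was 671 when each array was centred on its median, as chosen before the data were examined, and between 19 and 1609 when probe sets with equal or nearly equal control values were left out, an alternative added after seeing the data. With centring, 23 of the 24 genes named by size (all but LOC401261) and 98.4% of the probe sets past the size rule were called, and 10 of the 24 with equal control values left out. These were picked by size against the same controls. The smallest absolute difference called with centring was 0.77, below the size rule, so the high share gives no separate support. By size alone, 158 probe sets were at least 2-fold higher than each control and 149 were at least 2-fold lower. When control replicate 1 or 2 was set apart in the same way, 21 and 25 probe sets met the rule in either direction. By representative probe sets, 36 genes were higher and 57 lower, and the directions given for single genes below are differences in value, not calls.

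**Figure D1:**
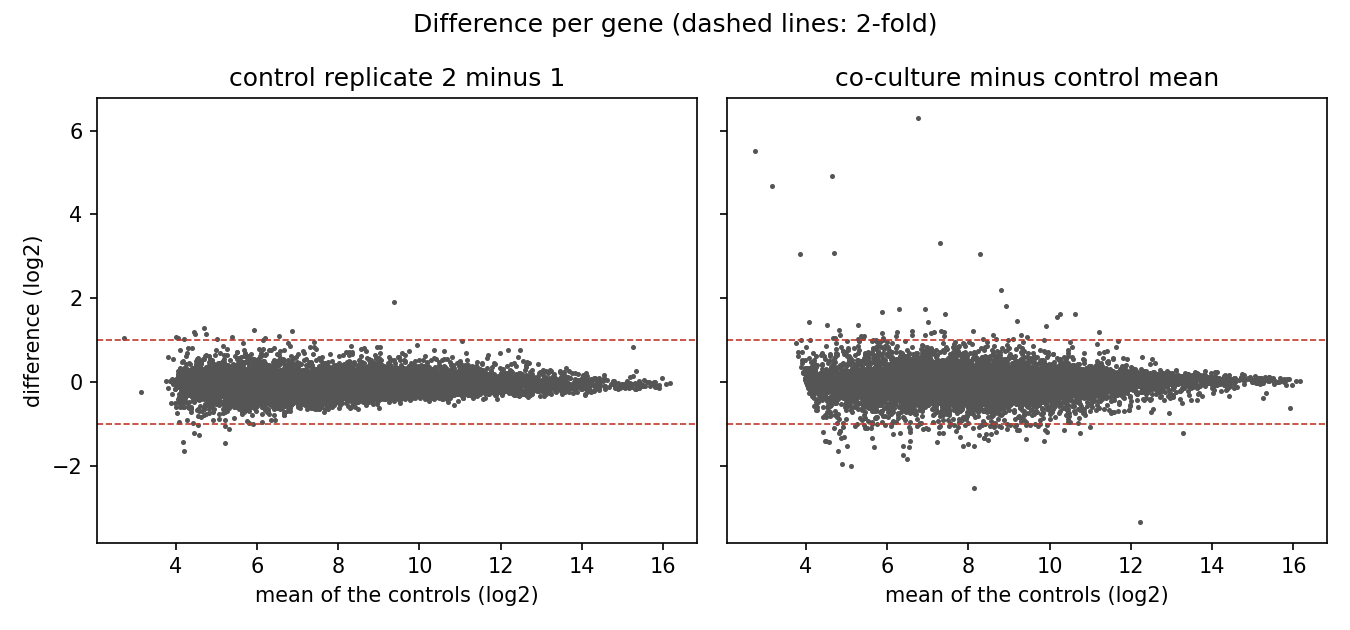
Difference per gene on the log2 scale (vertical axis) against the control mean (horizontal axis, log2) for 10783 genes, with control replicate 2 minus 1 on the left and co-culture minus control mean on the right. Dashed lines mark 2-fold; CCL20 is the highest point on the right at 6.30 and EGR1 the lowest at -3.35.

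Feedback genes of NF-kB had the largest median of the tested lists, described after the chemokines of the same pathway. Of 13 measured chemokines and cytokines of this pathway, 6 met the size rule as higher (CCL20, CXCL1, CXCL3, CXCL10, CXCL2 and CCL2), 0 as lower and 7 met neither. Differences were positive for 8 and negative for 5 (TNFSF15, IL18, CCL28, IL1B and LIF). The list median was 0.61, and 6 members passed when adjusted over the list alone. The filter takes the mean over all 3 arrays, so CXCL1, CXCL10 and CCL2 count as measured only through the co-culture array. With the filter on the control mean, an alternative added after seeing the data, 3 of 10 members met the size rule, the median was 0.23 and the list was not called (adjusted p = 0.125). At the main settings the list was called higher by camera (adjusted p = 0.00106), and the call was lost with an estimated correlation (adjusted p = 0.942). It was also lost when probe sets with shared sequence were left out (adjusted p = 0.0919), where the median was 0.23. The median also moved to 0.14 without the filter and to 1.97 at a mean log2 of at least 6, with the call kept in both. CXCL1, CXCL2 and CXCL3 are close paralogs, so their signals are uncertain to the extent that probes share sequence.

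Feedback and signalling genes of NF-kB were shifted more evenly. Positive differences were found for 17 of 18 measured members, the median was 0.96 and 4 members met the size rule. TNFAIP3, a ubiquitin-editing inhibitor of NF-kB, was 4.58-fold higher. NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, was 3.51-fold higher, the adhesion molecule ICAM1 2.31-fold and NFKBIZ 2.30-fold. Camera called the list higher (adjusted p = 5.33e-09; adjusted p = 0.942 with an estimated correlation), and 9 members passed when adjusted over the list alone against 0 over all genes tested. The median was 0.91 against control replicate 1 and 0.82 against control replicate 2, and 0.57 without probe sets of shared sequence. None of 10000 random lists of like expression reached this median.

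**Figure D2:**
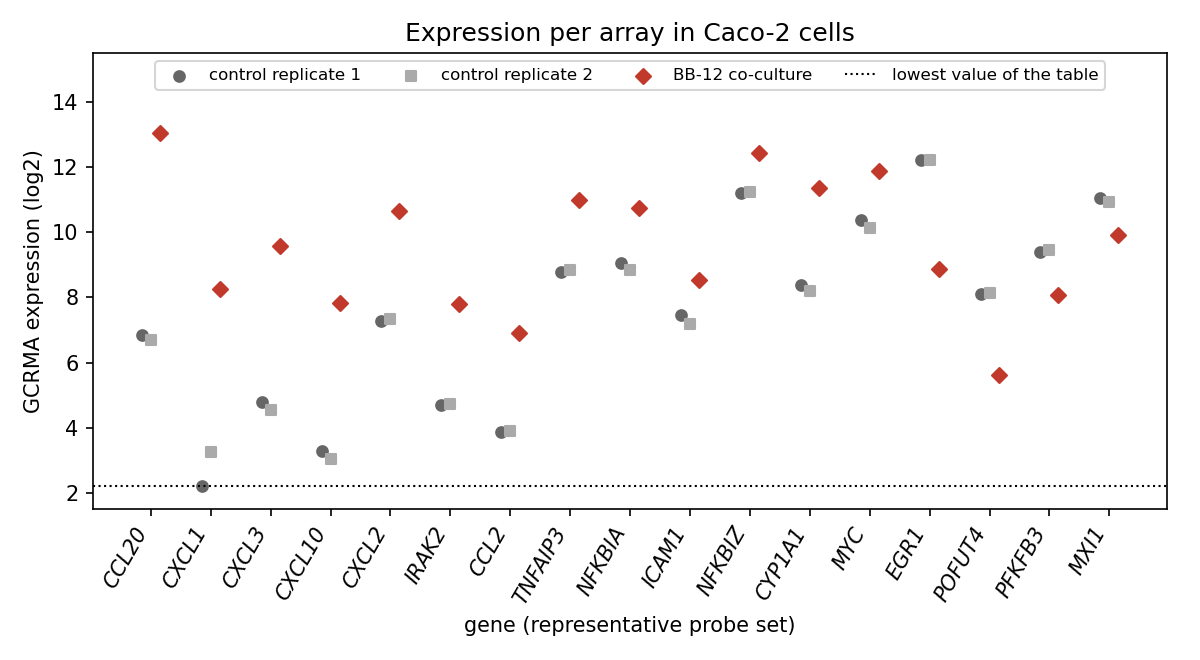
GCRMA expression (vertical axis, log2) of 17 genes (horizontal axis) on each array, with the controls as grey symbols, the co-culture array as red diamonds and the lowest value of the table as a dotted line. CCL20 reaches 13.06 in the co-culture array, against 6.84 and 6.68 in the controls, and EGR1 lies at 8.87 against 12.23 and 12.22.

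Genes that sense bacteria showed a smaller median. IRAK2, a kinase downstream of Toll-like receptors, was 8.47-fold higher, but the median of 12 measured pattern recognition genes was 0.09 (0.01 against control replicate 1 and 0.19 against control replicate 2) and the list was not called (adjusted p = 0.129). The interferon response was not called either (median -0.03, mean 0.27, adjusted p = 0.951). CXCL10 was its 1 member past the size rule, and IFIT1, an interferon-induced RNA-binding protein, had a difference of -0.56. Antigen presentation genes had a median of 0.18 (adjusted p = 0.129), with 0.05 against control replicate 1, 0.30 against control replicate 2 and -0.22 between the controls. Antimicrobial and mucosal defence genes had a median of 0.63 over 7 measured members and were not called (adjusted p = 0.0852), with DEFB1, an epithelial defensin, at 0.85 ± 0.20 (SE) and SLPI, a protease inhibitor, at 0.63 ± 0.10 (SE). The latter list passed under 4 alternatives, with adjusted p from 0.0120 to 0.0347.

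Growth-factor and immediate-early genes went both ways. MYC was 3.06-fold higher and EGR1 10.2-fold lower, JUN had a difference of 0.94 and IER2 of -0.81, and the median of 20 members was -0.11 (adjusted p = 0.511), with -0.23 against control replicate 1 and -0.04 against control replicate 2. Among MAP kinase phosphatases and feedback genes the median was 0.27 (adjusted p = 0.172). This list was called higher after repeated quantile normalization (adjusted p = 0.0492) and with centring (adjusted p = 0.0193), and its median was 0.08 against control replicate 1 and 0.43 against control replicate 2. DUSP5, which dephosphorylates ERK in the nucleus, was 3.06-fold higher, whereas DUSP1 had a difference of -0.75. SGK1, a serum- and glucocorticoid-regulated kinase, was 2.92-fold higher.

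Oxidative stress and xenobiotic genes were called higher with small medians. For NRF2 targets, 20 of 24 measured genes had positive differences, with a median of 0.19 (adjusted p = 4.91e-04; adjusted p = 0.942 with an estimated correlation). AKR1B10, an aldo-keto reductase, was 2.71-fold higher and SRXN1, which repairs peroxiredoxins, 2.34-fold. The NRF2 median was 0.10 against control replicate 1 and 0.30 against control replicate 2, and it also differed between the controls, at -0.17 for control replicate 2 minus 1. The list of aryl hydrocarbon receptor (AhR) and xenobiotic metabolism genes had a median of 0.16 over 20 genes (adjusted p = 0.0239; adjusted p = 0.942 with an estimated correlation). CYP1A1, a monooxygenase and the classical target of that receptor, was 8.29-fold higher and TIPARP 2.17-fold. This list lost its call without the filter (adjusted p = 0.126) and without probe sets of shared sequence (adjusted p = 0.0585), and its median was 0.10 against control replicate 1 and 0.20 against control replicate 2.

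Metallothioneins and zinc response genes had a median of 0.47 over 11 measured members, with 0 past the size rule (adjusted p = 0.0316; adjusted p = 0.942 with an estimated correlation). MT1X, MT1E and MT2A, small metal-binding proteins, had differences of 0.74, 0.67 and 0.54. These near-identical genes share probe sequence. Without probe sets of shared sequence the list median was 0.05 and the list could not be tested, so its shift rests on shared probe sets. The call was also lost without the filter (adjusted p = 0.128), and the median was 0.33 against control replicate 1 and 0.64 against control replicate 2. Ribosome biogenesis genes had a median of 0.19 over 19 members (adjusted p = 0.0182; adjusted p = 0.942 with an estimated correlation). NOP2 and NOP16, nucleolar proteins, had differences of 0.92 and 0.82. This median was 0.07 against control replicate 1 and 0.31 against control replicate 2, and the call was lost without the filter (adjusted p = 0.0501) and without probe sets of shared sequence (adjusted p = 0.0648).

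Heat shock and hypoxia genes were called lower. Of 20 measured heat shock genes, 16 had negative differences, with a median of -0.22 and 0 past the size rule (adjusted p = 3.95e-04; adjusted p = 0.942 with an estimated correlation). The co-chaperones DNAJB6 and DNAJB1 had differences of -0.84 and -0.58, and the chaperone HSPH1 -0.68. The median was -0.32 against control replicate 1 and -0.18 against control replicate 2. Hypoxia-inducible factor targets had a median of -0.16 over 20 genes (adjusted p = 0.00710; adjusted p = 0.942 with an estimated correlation). MXI1, a MYC antagonist, was 2.12-fold lower, and ADM, a vasodilator peptide, had a difference of 0.55.

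**Figure D3:**
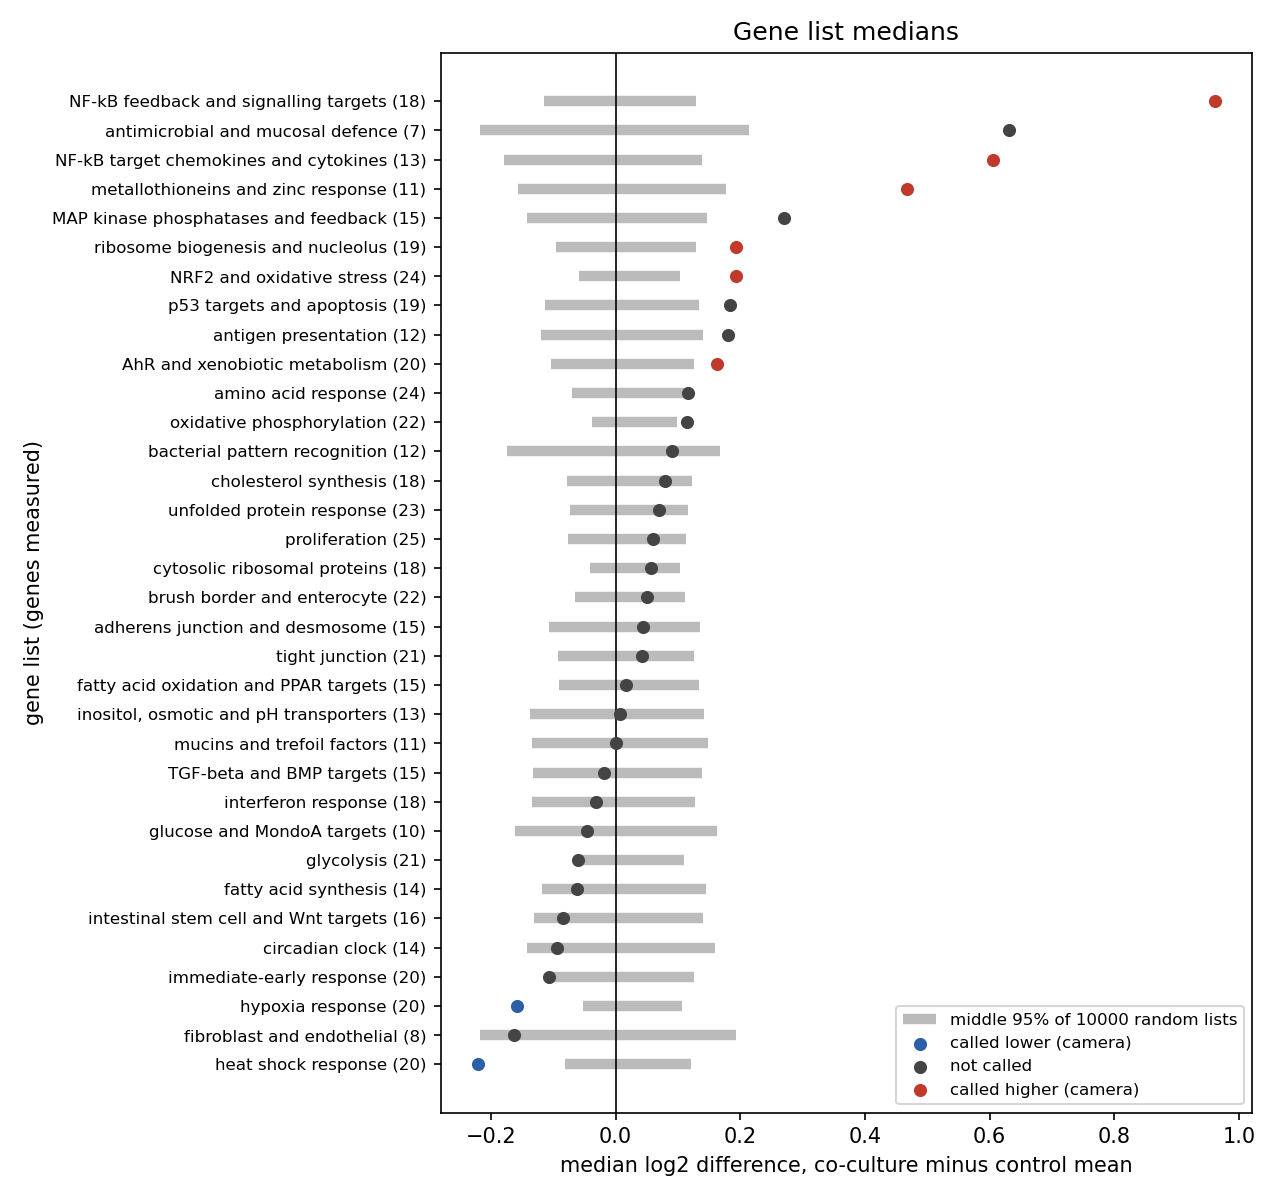
Median log2 difference between the co-culture array and the control mean (horizontal axis) for each tested gene list (vertical axis, genes measured in parentheses), with bars for the middle 95% of 10000 random lists of like expression and colours for the camera call. NF-kB feedback genes lie highest at 0.96 and heat shock genes lowest at -0.22.

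Metabolic and clock genes held single large differences without a list called at the main settings. PFKFB3, which makes the activator of phosphofructokinase, was 2.56-fold lower, and the glycolysis median was -0.06 (adjusted p = 0.143), with the list called lower after repeated quantile normalization (adjusted p = 0.0492). Its median was -0.10 against control replicate 1 and 0.02 against control replicate 2, so its direction depends on the control. PPP1R3B, a glycogen-targeting phosphatase subunit, had a difference of -1.20 in a list of glucose and MondoA targets with a median of -0.05 (adjusted p = 0.844). Of the 10 measured genes in that list, 4 had positive and 6 negative differences, with ARRDC4 highest at 0.87. The circadian transcription factors BHLHE41 and RORA were 2.87-fold and 2.54-fold lower, with a list median of -0.09 (adjusted p = 0.177). The value of RORA is that of 1 of its 5 probe sets, and their mean was 1.37-fold lower. Of the 14 measured clock genes, 6 had positive and 8 negative differences, with CRY1 highest at 0.56. ATF4 targets had a median of 0.12 but a mean of -0.03 (adjusted p = 0.761), with STC2 at -1.22 and the glutathione-degrading CHAC1 at -1.17. Cholesterol synthesis, fatty acid synthesis and fatty acid oxidation genes had medians of 0.08, -0.06 and 0.02, with adjusted p of 0.462, 0.511 and 0.844. Oxidative phosphorylation, the unfolded protein response and p53 targets had medians of 0.11, 0.07 and 0.18, with adjusted p of 0.172, 0.0818 and 0.143. The unfolded protein response was called higher without probe sets of shared sequence (adjusted p = 0.0463) and with the mean over probe sets (adjusted p = 0.0312).

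Barrier and differentiation genes showed no call. Tight junction genes had a median of 0.04 and a mean of -0.0056 over 21 members (adjusted p = 0.823), with the claudin CLDN2 at 0.61 and the scaffold PATJ at -0.89. Adherens junction and desmosome genes had a median of 0.04 (adjusted p = 0.699), and brush border genes a median of 0.05 over 22 members (adjusted p = 0.383), with KRT20 at 0.89. Mucins and trefoil factors, stem cell and Wnt targets, and TGF-beta and BMP targets had adjusted p of 0.797, 0.462 and 0.727. Proliferation genes and ribosomal proteins had medians of 0.06 and 0.06, with adjusted p of 0.460 and 0.462. Ion and osmolyte transporters had a median of 0.0063 (adjusted p = 0.699). Markers of fibroblasts and endothelium had a median of -0.16 (adjusted p = 0.177), and the enteroendocrine and leukocyte lists, with 2 measured genes each, were not tested. These p-values do not show that the lists were unaffected. Of the 26 tested lists that were not called, 24 had a median that moved more than 1.5 times or changed sign against 1 control alone.

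The remaining genes with the largest differences belong to no fixed list. TIMM23B, a mitochondrial import gene with close copies, and TAF5L, a chromatin complex subunit, were 3.35-fold and 3.34-fold higher. PTPRR, a tyrosine phosphatase, was 3.88-fold lower, and PRIMPOL, a primase-polymerase, had a difference of -1.56. ZNF623, HEATR5A, AFG2A, TNRC6B and PREX1 had differences of -1.83, -1.74, -1.54, -1.53 and -1.52. The transcripts LINC02421, SVIL-AS1 and LOC401261 had differences of -2.02, -1.66 and -1.55. With 1 co-culture array, none of these differences has a replicate check on the co-culture side. If the controls were taken at 0 hours, elapsed time and fresh medium differ together with the bacteria.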

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

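All tests in this part were chosen after the results were seen. Outside the comparison, 4 of 16 array control probe sets for human transcripts were higher in the co-culture array than in both controls by more than the gap between the controls. The differences lay between 0.19 and 0.46 on the log2 scale, and 1 of the 16 was lower by that rule. Among 42 spike-in control probe sets, which carry no sample RNA, 5 were higher by the same rule and 2 lower.

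NF-kB list genes stood above the controls in the co-culture array, where 10 of 31 were at least 2-fold off. Setting a control array apart in place of the co-culture array gave at most 1 such gene. CXCL1, CXCL10 and CCL2 are among the 10 and count as measured only through the co-culture array, which tilts this comparison. With the filter on the control mean, 3 of 10 chemokines and cytokines and 4 of 18 feedback genes were at least 2-fold higher. Over all 10783 genes at the main filter, 36 were higher and 57 lower by the size rule. The spread between arrays stays open all the same, because the control pools may differ by technical spread only and there is 1 co-culture array. By the 3-prime minus 5-prime difference, control 2 stood 0.25 (ACTB) and -0.012 (GAPDH) from control 1, and the co-culture array -0.061 and -0.010. The NF-kB median differed by -0.073 between the controls, against 0.89 between the co-culture array and control 1. RNA integrity stays open, because by ACTB the co-culture array lies outside both controls, -0.31 from control 2. Fresh medium and elapsed time instead of bacteria cannot be told apart from the bacteria, because 0 arrays are labelled as 4 hours without bacteria. The treatment protocol's control wells in the same set-up may be such arrays, but the labels disagree on this. A response to the bacteria is therefore 1 of several open explanations.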

How the results depend on the processing

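The alternatives on equal control values, the filter on the control mean and the percentiles against each control were chosen after seeing the data. The count of called probe sets was the least stable result. In place of 0 it was 1572 (1137 higher, 435 lower) without the filter, 1 (1 higher) at a mean log2 of at least 6, 1 (1 higher) after repeated quantile normalization and 671 (328 higher, 343 lower) with each array centred on its median. Without the filter, control arrays set apart gave 1385 and 1840 calls, so that count shows nothing specific to the co-culture array. Equal control values, found for 562 probe sets within 1e-09, lower the prior degrees of freedom. Leaving them out gave 19 calls (15 higher, 4 lower), and 273 with centring as well. Leaving out control values within 0.0001 of each other gave 83, and within 0.001 gave 1609. The count moved with the tolerance, all 4 settings were seen before any was chosen, and none is preferred. Control arrays set apart gave 0 calls in these 4 and with centring alone, which decides nothing, since the spread then included the co-culture array. The trend and robust priors, the stricter thresholds, the pseudocount and leaving out shared probe sets kept the count at 0.

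The size rule gave 85 higher and 77 lower at a mean log2 of at least 6, by construction with fewer probe sets, and 95 and 60 with a pseudocount of 16, which shrinks differences at low signal. Against 1 control alone it gave 258 to 303 higher and 246 to 287 lower, by construction a looser rule. The 39 named genes past the size rule (27 without shared probe sets) kept their direction throughout, mostly by construction. With the pseudocount 35 stayed at least 2-fold (not PTPRR, SVIL-AS1, AFG2A and CHAC1), and 37 with the mean over probe sets (not STC2 and RORA). With the filter on the control mean the size rule gave 138 higher and 162 lower, with 0 calls by the adjusted test, 5 lists called higher and 2 lower. There the NF-kB chemokine list lost its call (adjusted p = 0.125), since members low in the controls drop out. Lists called higher went from 6 to 3 without the filter and to 0 with an estimated correlation, where lists called lower went from 2 to 0. The cause was not tested. Lists called higher numbered 4 without shared probe sets, 7 at a mean log2 of at least 6 and with the mean over probe sets, and 8 after quantile normalization or centring, and lists called lower numbered 3 after quantile normalization. The NF-kB, NRF2, metallothionein, AhR and xenobiotic, heat shock and hypoxia lists lay outside the middle 95% of random lists against each control alone. So did the antimicrobial and p53 lists, which were not called at the main settings. Ribosome biogenesis, which was called, lay at the 96.5th percentile against control 1. Between the controls themselves 7 of 36 lists lay outside that range, among them NRF2 at the 0.50th percentile, so such a position does not by itself set the co-culture array apart. The robust prior was not run for the lists, since camera has no such option. No paired analysis was possible because there is 1 co-culture array. Values near the floor of 2.22 carry little signal over background and limit folds such as that of CXCL1.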

Other observations

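All genes named in this part were chosen after their values were seen, and all tests in it were chosen after the results were seen. Beyond the fixed lists, several signalling genes met the size rule without passing the adjusted test at the main settings. RCAN1, an inhibitor of calcineurin, was 3.09-fold higher, IL4R, a cytokine receptor chain, 3.19-fold, EREG, an EGF receptor ligand, 2.52-fold and PTGS2, the inducible cyclooxygenase, 2.37-fold. STC1, a secreted glycoprotein, was 2.72-fold lower, PTCH1, the hedgehog receptor, 2.27-fold and TSC1, an inhibitor of mTORC1 signalling, 2.14-fold.

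One pattern concerns genes with several probe sets. Of the probe sets at least 2-fold higher and annotated with 1 gene, 76 were not the representative of their gene, and for 51 of them the representative differed by less than 0.5. Minor probe sets made up 67.9% of these higher probe sets, against 45.1% of all tested probe sets with 1 gene. Among the lower ones, 61 were minor and 30 of those had a flat main probe set. Minor ones made up 51.7% of the lower probe sets, so the excess over all tested ones lies mainly on the higher side. GART, a purine synthesis enzyme, is an example. Its minor probe set was 4.52 and 4.78 in the controls and 3.35 higher in the co-culture array, while its main probe set differed by -0.25. EED, a Polycomb protein, and ATP5F1C, an ATP synthase subunit, had minor probe sets 2.61 and 2.32 higher, with main probe sets at -0.25 and 0.08. Setting a control array apart gave at most 6 such probe sets, but few probe sets were higher there at all. Such minor probe sets made up 5 of 7 and 6 of 15 of them, against 51 of 158 for the co-culture array, so the spread between arrays stays open. Unspliced RNA, genomic DNA or another isoform stays open: the median of all 3460 minor probe sets at least 4-fold below the main one was 0.021, with a 95th percentile of 0.75, and probe positions were not used here.

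Another pattern is the presence of zinc finger genes among the lower genes. Of the 57 genes lower by size, 8 carry zinc finger gene symbols (ZNF, ZKSCAN, ZSCAN or ZFP), among them ZKSCAN1 at -1.15 and ZNF782 at -1.33, against 0 of the 36 higher genes. The class was noticed among these same genes, so a draw of genes of like level was tested over all 54 symbol families with at least 20 tested genes. Some family was as enriched in a share of 0.0373 of random sets, which leaves chance open, since only lower genes and families by symbol were scanned. The median of all 343 zinc finger genes was -0.051, which lay below all 10000 random lists, and -1.24 for the 8 lower ones. On this co-culture array the class as a whole was therefore not lower by the size of those 8, which were picked by size. A smaller shift of the class stays open, because there is 1 co-culture array. No biological explanation was tested for the patterns in minor probe sets and zinc finger genes.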
